A study of Homo sapiens with 2 samples.

How the data were processed

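Gene expression was measured in 2 stable derivatives of MCF-7, an estrogen receptor-positive human breast cancer cell line with epithelial character. Per the labels, one derivative expressed wild-type histone H2A.Z (WT) and the other H2A.Z with a lysine-to-glutamine substitution (K102Q), both from lentiviral vectors, while endogenous H2A.Z was knocked down by a lentiviral short hairpin construct. Knockdown cells were selected in 1 µg/ml puromycin for 3 days, per the labels. Total RNA was extracted with Trizol, labelled with biotin and hybridized to Affymetrix Human Genome U133 Plus 2.0 arrays, per the labels and the series design. There was 1 array per group, 2 arrays in all, so no estimate of the spread between cultures exists and no test of a difference could be made.

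The deposited table holds 1 intensity per probe set and array, on a linear scale, for 54675 probe sets. A probe set is a group of short probes that target one transcript. The software that summarized and normalized the intensity values is not given in the sources used here. The 2% trimmed mean (2% of values removed at each end) of the deposited intensity was 500.1 on both arrays, as scaling of each array to a common target gives. The 75th percentiles of the arrays were 457.5 (WT) and 467.2 (K102Q), 0.03 apart on the log2 scale and below the tolerance of 0.1, so the values were used as deposited, with no further normalization.

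The following choices were made before the data were examined: the working limit, the fold sizes, the gene lists, the rule for named genes and the main set of alternatives. Intensities were put on the log2 scale, and differences are K102Q minus WT. A working limit was set at the 50th percentile of the pooled values of both arrays, a signal of 101.7, and lower values were set to it. A probe set under the limit on both arrays counted as not measured. Where only one array was above the limit, the difference is a bound and is written as "at least N-fold". The 62 control probe sets were left out of gene values.

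Probe sets were named through the platform's gene table, with symbols updated by Entrez identifier to the gene table of assembly GRCh38.p14, which served only for names and for the order of neighbouring genes. Of the probe sets, 41097 had 1 symbol, 1801 had several and 11777 had none in that table, and only those with 1 symbol were used. Identifiers of 41043 matched. They covered 19775 genes, of which 12644 were measured, 11278 of them on both arrays and 1366 on one. A gene took the value of its probe set with the highest mean log2 signal, and its other probe sets served as a check.

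Genes at least 2-fold and at least 1.5-fold apart were counted, with no p-value. Measurement error within the arrays was taken from the disagreement between probe sets of the same gene and from 18 hybridization controls, which are transcripts spiked into each sample. For each of 38 gene lists, the median log2 difference of the measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list below the 2.5th or above the 97.5th percentile is described as standing apart. This describes the 2 arrays and is no test between genotypes. A list needed 5 measured members. Intervals for list medians are 95% bootstrap intervals over the members (2000 draws).

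The genes named in the text follow a rule: H2AZ1, H2AZ2, CCNA1, SMYD2 and SMYD3 whatever their values; the 12 genes per direction with the largest difference among those above the limit on both arrays whose other probe sets, if any, had a median of the same sign; the 4 per direction with the largest bound; and from each list up to 2 members per direction at least 1.5-fold apart. Genes outside this rule are marked where they appear. CCNA1 is known from earlier work on this system as a target of H2A.Z methylation, so its value is not independent evidence.

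Alternatives were quantile normalization, median centring, lowess correction with a fraction of 0.3, working limits at the 30th and 70th percentile or none, the mean of all probe sets of a gene, leaving out probe sets that can bind several transcripts (names ending in _x_at or _s_at), and log2(value + 16) with no working limit. For the lists, they were also 10 bins, leaving out shared members, and the mean. The pipeline was tested on simulated data. With 200 genes altered among 11278 and noise drawn from the probe set disagreements, the 2-fold rule found 48.4% of genes with a true log2 difference of 1, 99.4% at 2 and 100.0% at 3. At 1 the true difference equals the cutoff, so the symmetric noise largely fixes that share in advance. The noise held no spread between cultures or lines, so these shares are not the sensitivity of this design. Of 500 random lists with no shift, 5.40% fell beyond the 2.5th or 97.5th percentile. Noise was independent between genes there, so this does not test lists whose genes vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.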

Results

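The study asked how gene expression differed between MCF-7 cells whose H2A.Z was supplied as the WT protein and cells supplied with the K102Q mutant. H2A.Z is a variant of histone H2A found at promoters and other regulatory sites. SMYD3 is an enzyme known to methylate it. Expression was measured on 1 array per group, with 54675 probe sets each. The arrays had nearly the same share of probe sets above the working limit, 49.4% for WT and 50.6% for K102Q. Signals of the 3' and 5' ends of control transcripts, a sign of RNA integrity, had similar ratios on both arrays, 1.21 and 1.16 for GAPDH and 1.69 and 1.77 for ACTB. Log2 signals correlated across probe sets with a Pearson r of 0.909 over all and 0.980 above the limit. Probe sets are not independent replicates. No value below has a replicate, and the number of arrays limits the precision.

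H2AZ1, the gene for the main form of H2A.Z and the target of the knockdown, had a signal of 5010 on the WT array and 4611.7 on the K102Q array, a log2 difference of -0.12. Its other probe set read 3517.2 and 1941.5, a log2 difference of -0.86, so the probe sets disagreed by more than the usual error. No array of unmodified cells was analysed here, and whether a probe set separates the supplied from the endogenous transcript was not examined. The values therefore check neither the knockdown nor the labels. H2AZ2, the gene of the second form of H2A.Z, differed by -0.07, and its other 3 probe sets had a median of -0.02. SMYD3 differed by -0.07 on the 1 probe set above the limit. SMYD2, a related methyltransferase, differed by 0.20, with 0.73 on a dimmer probe set. CCNA1, which encodes cyclin A1 and is the known target in this system, had a signal of 372.9 on the WT array and 132.5 on the K102Q array. It was 2.81-fold lower in K102Q (log2 difference -1.49). That value rests on 1 probe set close to the working limit, and with the limit at the 70th percentile it shrinks to a bound of -0.20.

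The most pronounced differences were of single genes that were far brighter on the K102Q array. LGALS4, which encodes the sugar-binding lectin galectin-4, was below the limit on the WT array and had a signal of 4712.3 on the K102Q array, at least 46.3-fold higher. The bound follows the limit, and on the log2 scale it was 5.53 here and 3.86 with the limit at the 70th percentile. ERCC1, a subunit of the nuclease of nucleotide excision repair, was 20.4-fold higher (854 against 17418.3), and AGO3, an Argonaute protein that binds small RNAs, was 18.5-fold higher (549.9 against 10171.8). The other 2 AGO3 probe sets above the limit on both arrays read less, at 1.89 and 2.13 log2. EPB41L4A, a member of the band 4.1 protein family, was 9.14-fold higher. On the other side, CALB2, which encodes the calcium-binding protein calretinin, was 5.75-fold lower in K102Q, and EAF2, a partner of the elongation factor ELL, was 5.03-fold lower. CRB1, a cell polarity protein, had a signal of 757 on the WT array and was at least 7.44-fold lower on the K102Q array.

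Further genes higher in K102Q were the cyclic AMP phosphodiesterase PDE4D (6.77-fold), the beta-catenin cofactor BCL9 (4.61-fold) and the steroid-converting enzyme AKR1C3 (4.57-fold). MROH1 was 4.06-fold higher on one probe set and differed by 0.11 log2 on its other. The transcription factor MITF was 3.71-fold higher, with 2.07 log2 on its other probe set. IGFBP5, which binds insulin-like growth factors, was 3.36-fold higher, with 0.62 log2 on its other probe set. HOXC4, NUP42 and SPN were 3.27-fold, 3.23-fold and 3.05-fold higher. B3GALT5, GPC6 and CLDN19 were at least 5.23-fold, 3.59-fold and 2.79-fold higher. Another B3GALT5 probe set, above the limit on both arrays, read 0.68 log2. Genes lower in K102Q included the actin-associated SYNPO (4.05-fold, although 2 dimmer probe sets above the limit only on the K102Q array read 0.46 and 0.15 log2), the noncoding RNA LINC00052 (3.60-fold), GIN1 (3.26-fold), the scaffold protein PDZK1 (3.24-fold), COL12A1, a fibril-associated collagen (3.23-fold), and CPSF3, the nuclease that cleaves the 3' ends of pre-mRNA (3.19-fold). PRKAR1B, CCDC171, C21orf58 and COXFA4L3 were 3.13-fold, 3.11-fold, 3.02-fold and 2.88-fold lower. The other probe sets of PRKAR1B and CCDC171 read only -0.17 and -0.19 log2. RASGRP1, ERN2 and GUSBP11 were at least 3.66-fold, 3.23-fold and 3.10-fold lower. RASGRP1 lies among the 20 neighbouring genes from FAM98B to KNL1, which had a median of -0.57 log2. COXFA4L3 lies among the 20 from MFAP1 to CEP152, which had a median of -0.53 with 19 lower. Many of the single genes named here were dim on at least one array, and with the limit at the 70th percentile their values became smaller bounds. These were -1.02 log2 for CALB2, -1.50 for EAF2, -0.45 for SYNPO, -0.40 for LINC00052, -0.53 for PDZK1, 0.81 for HOXC4, 0.40 for NUP42, 0.23 for SPN, 1.92 for PDE4D, -0.27 for CCDC171, -0.33 for C21orf58 and -0.77 for COXFA4L3. Among the genes given above as bounds, they were 0.72 for B3GALT5, 0.17 for GPC6, -1.22 for CRB1, -0.20 for RASGRP1 and -0.019 for ERN2. PRKAR1B, CLDN19 and GUSBP11 were below that limit on both arrays. DDX50, an RNA helicase gene outside the naming rule and chosen after its values were seen, was 17.5-fold higher on one probe set (1889.4 against 32975.1) and differed by -0.01 log2 on its other.

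**Figure D1:**
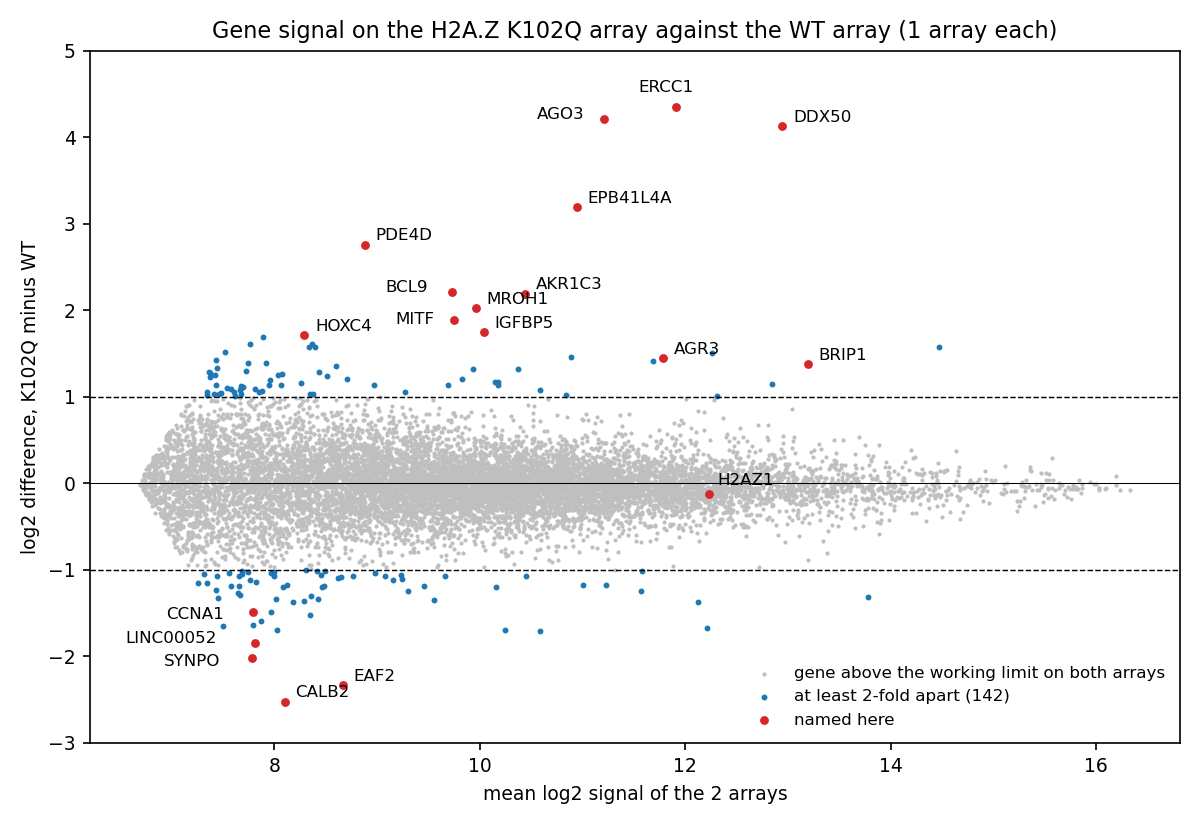
Each point is a gene above the working limit on both arrays, with the mean log2 signal of the 2 arrays on the x axis and the log2 difference, K102Q minus WT, on the y axis, and dashed lines at 2-fold. ERCC1 (4.35), AGO3 (4.21), DDX50 (4.13) and EPB41L4A (3.19) are the 4 highest, followed by PDE4D (2.76), CALB2 (-2.52) is the lowest, and H2AZ1 (-0.12) lies near 0.

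In all, 201 of 12644 measured genes were at least 2-fold apart, 108 higher and 93 lower in K102Q, and 1216 were at least 1.5-fold apart, 636 higher and 580 lower. Higher genes thus made up 53.7% of the 2-fold set, and 41.8% after each array was centred on its median, so the balance of directions depends on the scaling. Of the 201 genes, 142 were above the limit on both arrays. Probe sets of the same gene disagreed with an SD of 0.30 log2 (5533 genes), from 0.39 for the dimmest to 0.20 for the brightest of 4 signal groups. Arrays simulated with this noise alone gave a median of 42 and at most 56 genes at least 2-fold apart in 100 draws, against the 142 observed. At 1.5-fold they gave a median of 535 and at most 583, against 979. Among 49 of the 2-fold genes with another probe set above the limit, 42 (85.7%) had the same sign there, and 22 were also at least 1.5-fold apart in that direction. The share was 73.6% among the 1.5-fold genes and 60.9% among genes with smaller differences. The 18 hybridization controls differed by a median of -0.04, with a range from -0.20 to 0.23.

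Cell cycle genes were lower on the K102Q array as a group. All 38 genes of the G2/M and mitosis list were measured and 34 were lower in K102Q. Their median log2 difference was -0.30 (95% interval -0.41 to -0.24), lower than that of all 10000 matched random lists. BUB1B, a kinase of the spindle checkpoint, differed by -0.79, and KIF23, a motor protein of cytokinesis, by -0.80, although the second probe set of KIF23 read 0.39. BUB1B lies among the 20 neighbouring genes from FAM98B to KNL1, which had a median of -0.57, and KIF23 lies on the same chromosome. Without genes of chromosomes with such runs, a choice made after the results were seen, the G2/M list had a median of -0.25. In the G1/S and DNA replication list, 24 of 36 genes were lower, with a median of -0.24 (-0.33 to -0.02), again lower than all random lists. CLSPN, a mediator of the replication checkpoint, differed by -1.01. E2F1, a transcription factor of the G1/S transition, differed by -0.96 on one probe set and by 0.35 on the other. POLA1, the catalytic subunit of DNA polymerase alpha, was higher, at 0.63. Of 19 cyclins and cyclin-dependent kinases, 16 were lower, with a median of -0.23 (-0.34 to -0.14), and 4 of the 10000 random lists had a lower median. CCNE2, cyclin E2, differed by -0.80 on one probe set and by 0.14 on the other. Most of these differences are small for single genes. Of the members of the 3 lists, 3, 3 and 4 were at least 1.5-fold lower among the cyclins, the G1/S genes and the G2/M genes. Leaving out CCNA1, a choice made after the result was seen, gave -0.23 for the cyclin list. On the other probe sets of 10 of its genes, the cyclin list had a median of -0.15 and did not stand apart (percentile 5.07).

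**Figure D2:**
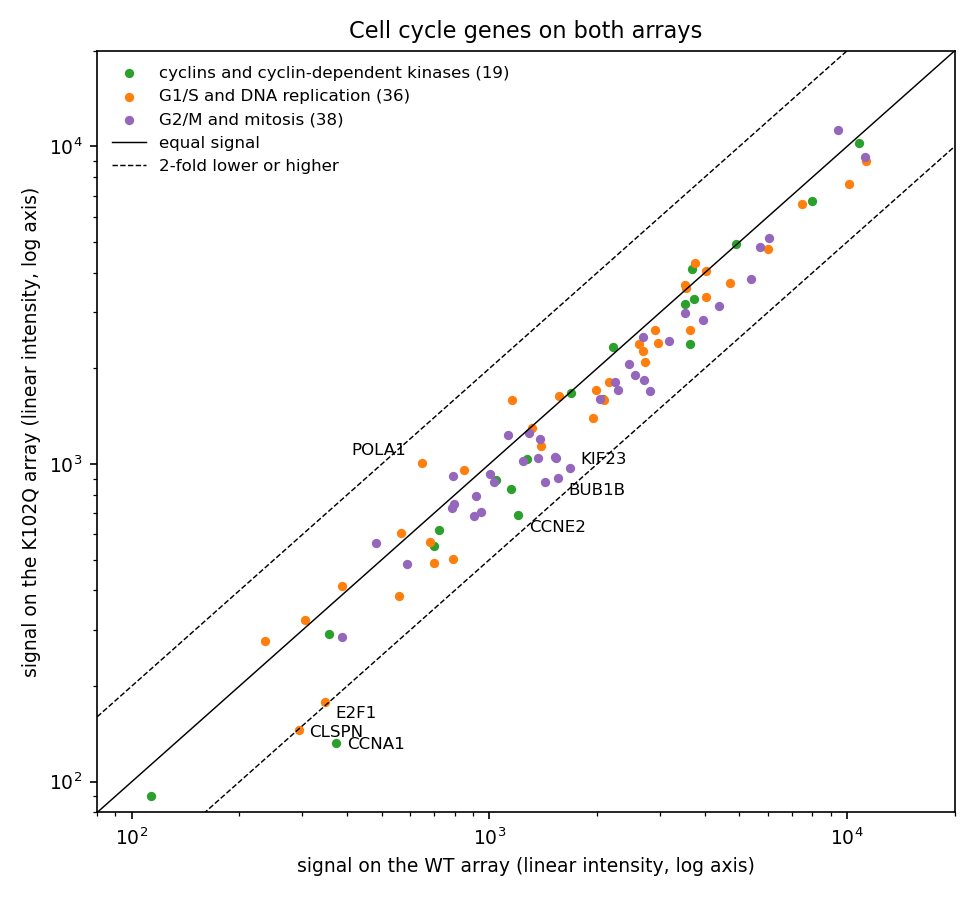
Each point is a gene of the cyclin, G1/S or G2/M list, with its signal on the WT array on the x axis and on the K102Q array on the y axis (linear intensity, both axes logarithmic), a solid line at equal signal and dashed lines at 2-fold. Most points, among them 34 of the 38 G2/M genes, lie below the solid line but within 2-fold, and CCNA1 lies clearly below the lower dashed line.

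The lists tied to the cell cycle in other ways were mixed. Histone genes had a median of -0.16 over 17 measured members, 15 of them lower, and 241 of the 10000 random lists were lower still. This list stood apart under 8 of 13 alternatives, and its percentile was 35.6 without _x_at and _s_at probe sets. The inhibitors of cyclin-dependent kinases and pocket proteins did not stand apart, at -0.12 over 8 genes (percentile 10.9). Homologous recombination and DNA damage response genes had a median of -0.10 over 26 genes (percentile 8.41). In that list BRIP1, the helicase that binds BRCA1, was 2.60-fold higher in K102Q (5809.5 against 15118.3), with 1.93 log2 on its other probe set, and RAD54B, a recombination protein, was 2.37-fold lower.

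In estrogen signalling, which drives growth of MCF-7 cells, known targets of the estrogen receptor had a median of -0.11 over 40 genes, 25 of them lower (percentile 2.77), which is close to the edge. The list did not stand apart under 10 of 13 alternatives, but did as low with the mean of all probe sets (-0.16, percentile 0.06), with the mean in place of the median and with log2(value + 16), as well as on its other probe sets. Among them, PDZK1 was 3.24-fold lower and the small heat shock protein HSPB8 was 2.36-fold lower, with only -0.47 log2 on its other probe set. MYC was 1.60-fold higher and IL17RB was 1.62-fold higher, although IL17RB was at 0.026 log2 with the limit at the 70th percentile. Genes known to be repressed by estrogen had a median of 0.26 over 14 genes, 9 of them higher, and 9999 of the 10000 random lists lay below. Its 95% interval, -0.06 to 0.41, reached below 0, and its mean of 0.11 did not stand apart. PSCA was 1.58-fold higher in that list, and CYP1A1, the xenobiotic-metabolizing enzyme, was 2.29-fold lower. Markers of luminal epithelium had a median of 0.03 over 23 genes (percentile 94.4). The list did not stand apart there or under 9 of 13 alternatives, but stood apart as high under the other 4, with a median of 0.35 without _x_at and _s_at probe sets. The secreted-protein gene AGR3 was 2.74-fold higher and TBX3, a T-box transcription factor, was 1.59-fold higher. Basal and stem-like markers (0.10 over 10 genes, percentile 83.1) and mesenchymal genes (-0.04 over 13 genes, percentile 34.5) did not stand apart either. EGFR was 1.67-fold lower, SOX9 1.72-fold higher, PLAUR 1.75-fold higher, TGFBI 1.54-fold lower and TAGLN 1.70-fold lower. Other probe sets read -0.28 log2 for EGFR and 0.32 for SOX9. A PLAUR probe set above the limit only on the WT array read -0.20. A TAGLN probe set above it only on the K102Q array read 0.67, and another, above it only on the WT array, read -1.01.

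Targets of Wnt signalling were higher in K102Q, with a median of 0.34 over 12 genes (0.06 to 0.62), 11 of them higher, and 9988 random lists lay below. The list no longer stood apart with no working limit (0.15, percentile 90.1), with log2(value + 16) or without _x_at and _s_at probe sets. RNF43, a ubiquitin ligase that dampens Wnt signalling, was 1.72-fold higher. Targets of p53 had a median of 0.15 over 27 genes (0.04 to 0.22), 19 of them higher, and 9987 random lists lay below. Only AEN, a nuclease, passed 1.5-fold among them (1.51-fold), and the other probe sets of the 12 p53 targets that had one gave a median of 0.06 (percentile 69.9). Metallothionein and oxidative stress genes had a median of 0.12 over 23 genes (-0.09 to 0.34), with 9953 random lists below. This list stood apart under 10 of 13 alternatives, and its percentile was 83.4 without _x_at and _s_at probe sets. AKR1C3 and MT1E (1.97-fold) led the list, but a second probe set of MT1E read -0.16. TGF-beta and BMP genes (0.02 over 20 genes, percentile 79.5) and Notch genes (0.01 over 10, percentile 57.4) did not stand apart. BMP4, a growth factor, was 2.39-fold higher (a bound of 0.32 log2 with the limit at the 70th percentile), the receptor TGFBR2 was 1.56-fold lower, and PMEPA1 differed by -0.74, with -0.04 on its other probe sets.

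Among stress and immune genes, the unfolded protein response list had a median of -0.14 over 22 genes (percentile 1.90), with its transcription factor DDIT3 2.02-fold lower. It stood apart under only 5 of 13 alternatives, and on other probe sets it had a median of -0.0080. Heat shock proteins and chaperones were at -0.16 over 15 genes (-0.24 to 0.03, percentile 0.955), with HSPB8 the lowest. That interval reached above 0, and HSPB8 read only -0.47 log2 on its other probe set. Amino acid starvation genes were at -0.12 over 25 genes (percentile 2.96, not apart). SLC3A2, the heavy chain of amino acid transporters, was 2.00-fold lower, and MTHFD2, a mitochondrial folate enzyme, was 1.85-fold lower on its bright probe set and differed by 0.44 on a dim one. Type I interferon genes had a median of -0.18 over 24 genes (-0.31 to 0.12, percentile 1.60), with an interval that also reached above 0. HERC5 and CMPK2 were 1.53-fold and 1.52-fold lower and PARP14 1.61-fold higher, and this list stood apart under 4 of 13 alternatives. Antigen presentation genes of MHC class I were at -0.06 over 12 genes (percentile 31.2), with TAP2 1.73-fold higher (0.18 log2 on its other probe set), and NF-kB and cytokine genes at 0.04 over 13 (percentile 57.5), with ICAM1 1.51-fold lower but at 0.18 log2 on the mean of its probe sets. Immediate early genes were at -0.01 over 25 genes (percentile 55.5), with EGR1 1.96-fold higher and SRF 1.66-fold lower. Apoptosis regulators were at 0.08 over 22 genes (percentile 94.4), with BAK1 1.85-fold lower.

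In metabolism, oxidative phosphorylation genes had a median of -0.11 over 34 genes, 23 of them lower, just past the edge at percentile 2.40. It stood apart under 9 of 13 alternatives, and no member was 1.5-fold apart. Glycolysis (-0.04 over 17 genes, percentile 51.0), hypoxia response (0.02 over 25, percentile 79.8), cholesterol synthesis (-0.08 over 18, percentile 19.5) and fatty acid synthesis (0.01 over 12, percentile 66.0) did not stand apart. ENO2, a glycolytic enolase, was 1.95-fold higher, whereas ADM, a hypoxia-induced peptide, was 1.92-fold lower, ANKRD37 1.88-fold lower and MVD 1.67-fold lower. ELOVL6, a fatty acid elongase, was 2.02-fold lower on one probe set, with a median of 0.13 on its other probe sets, and FADS2, a fatty acid desaturase, was at least 1.56-fold higher. Cytosolic ribosomal proteins (-0.04 over 38 genes, percentile 61.4) and ribosome biogenesis genes (-0.07 over 24, percentile 20.3) did not stand apart. RRP12 differed by -0.68 in the latter, with 0.06 on its other probe sets.

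The genes that place or remove H2A.Z had a median of 0.01 over 25 genes (percentile 74.98), with no member 1.5-fold apart. Histone lysine methyltransferases and demethylases were at -0.01 over 34 genes (percentile 55.7), with SETD1A 1.60-fold lower. Cell adhesion and junction genes were at -0.09 over 26 genes (percentile 12.9), with CLDN1 1.73-fold lower. Markers of endothelial cells, as a check for other cells, were at 0.05 over 5 genes (percentile 51.8). Among its members, ERG was at least 2.47-fold higher, with 0.15 log2 on another probe set above the limit only on the K102Q array, and PECAM1 and EGFL7 were 1.65-fold and 1.56-fold lower. Lists for fibroblasts, leukocytes and HEK293-type kidney and neural cells had only 4, 3 and 4 measured members and got no percentile. Of the 35 lists with a percentile, 8 stood apart as low and 4 as high. For lists of genes that vary independently, 1.75 would be expected. The lists share members and hold genes that can vary together, so this comparison cannot show an excess over chance. The sign of some small list medians depends on the scaling, although of no list that stood apart. With median centring, the medians of the H2A.Z deposition, luminal, NF-kB, hypoxia, fatty acid synthesis, TGF-beta, Notch and endothelial lists were below 0. With quantile normalization and with lowess correction, the NF-kB, Notch and endothelial medians were below 0, and those of the methyltransferase and demethylase list and of the ribosomal proteins above 0.

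**Figure D3:**
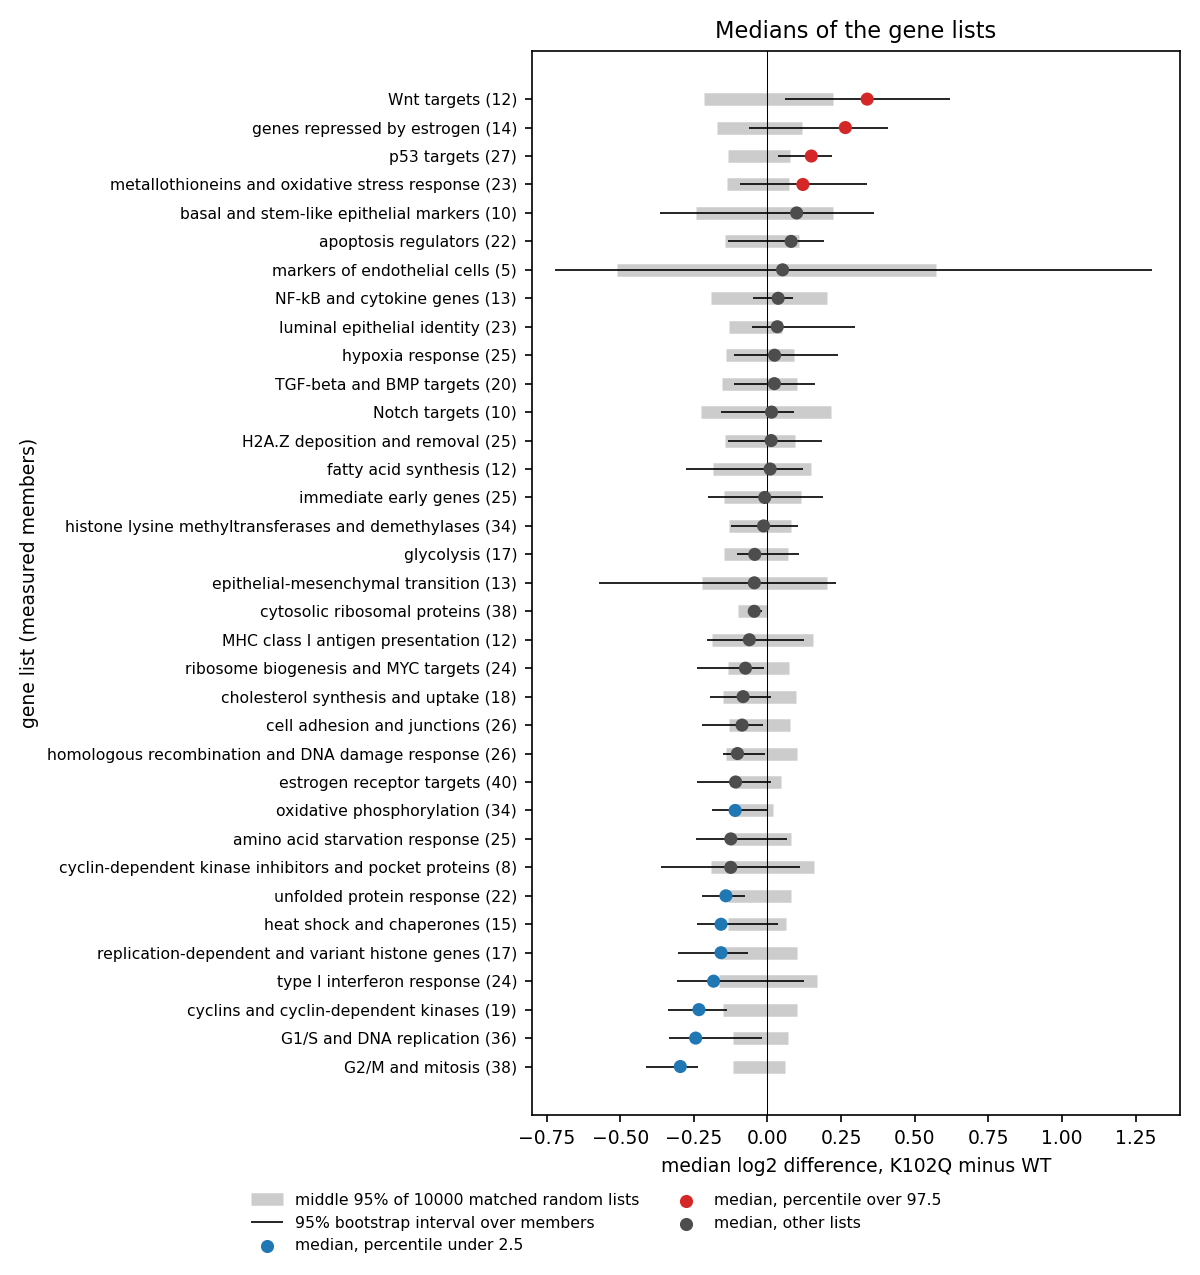
Each dot is the median log2 difference, K102Q minus WT, of a gene list (x axis), with the number of measured members beside its name (y axis), grey bars for the middle 95% of 10000 matched random lists and thin lines for the 95% bootstrap interval over members. The G2/M (-0.30), G1/S (-0.24) and cyclin (-0.23) lists lie lowest, and Wnt targets (0.34) highest.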

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

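Alternatives with other probe sets, without CCNA1 and without genes of chromosomes with neighbour runs were chosen after the results were seen. The 3 cell cycle lists stood apart as low under all alternatives chosen beforehand, without CCNA1 and without those chromosomes, with medians from -0.32 to -0.21 (cyclins), -0.32 to -0.19 (G1/S) and -0.39 to -0.25 (G2/M). The exception was the cyclin list on other probe sets. The counts of genes apart were higher with a lower working limit or none. Genes at least 2-fold apart numbered 817 with the limit at the 30th percentile, 53 at the 70th, 3567 with no limit and 2198 with log2(value + 16), which also has no limit. Genes at least 1.5-fold apart numbered 3011, 448, 6110 and 4724 in the same order. Signal over background limits which genes enter these counts. The cause of the list shifts below was not tested.

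Of the lists that stood apart, these moved or no longer stood apart. Quantile normalization gave interferon -0.19 and unfolded protein response (UPR) -0.12. Median centring gave histone -0.24 and oxidative phosphorylation (OXPHOS) -0.19. Lowess gave histone -0.13 and interferon -0.18. The 30th percentile limit gave interferon -0.013 and UPR -0.13, and the 70th gave histone -0.16, interferon -0.040 and UPR -0.13. No limit gave interferon -0.011, UPR -0.13 and Wnt 0.15, and log2(value + 16) gave -0.011, -0.12 and 0.14. The mean of all probe sets gave histone -0.086, interferon -0.087, UPR -0.051 and OXPHOS -0.080. Leaving out _x_at and _s_at probe sets gave histone -0.057, UPR -0.12, OXPHOS -0.12, heat shock -0.24, metallothionein 0.073 and Wnt 0.23. Leaving out shared members gave metallothionein 0.072. The mean in place of the median gave estrogen-repressed 0.11, interferon -0.088, UPR -0.13 and OXPHOS -0.093. Other probe sets gave cyclins -0.15, histone -0.10, p53 0.063, UPR -0.0080, OXPHOS -0.027 and metallothionein 0.15. Without the chromosomes with runs, interferon was -0.082, OXPHOS -0.12 and metallothionein 0.072. Other lists came to stand apart. As low, these were estrogen receptor targets with the mean of all probe sets (-0.16), the mean (-0.13), log2(value + 16) (-0.11) and other probe sets (-0.16), amino acid starvation with the mean (-0.16), cell adhesion without _x_at and _s_at probe sets (-0.22), and ribosome biogenesis without the chromosomes with runs (-0.22). As high, these were luminal markers with the mean of all probe sets (0.083), without _x_at and _s_at probe sets (0.35), without shared members (0.19), with the mean (0.17) and on other probe sets (0.18), mesenchymal genes without _x_at and _s_at probe sets (0.29), and fatty acid synthesis on other probe sets (0.26).

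Sign changes among named genes came from probe sets that disagree. Without _x_at and _s_at probe sets, E2F1 read 0.35, KIF23 0.39, TAGLN 0.67 and RRP12 0.27, and with the mean of all probe sets ICAM1 read 0.18. Of 739 values of named genes under the alternatives, 664 moved by less than the probe set SD of 0.30, 70 by more, and 5 changed sign. At the 70th percentile limit, further dim named genes became smaller bounds. Among them, DDIT3 read -0.66, EGFR -0.17, SOX9 0.40, SRF -0.43, MVD -0.20 and EGFL7 -0.21. At that limit no value could be had for CLDN19, CLSPN, CMPK2, ERG, FADS2, GUSBP11, HERC5, ICAM1, PARP14, PECAM1, PLAUR, PRKAR1B, SETD1A, TAGLN, TAP2 and TBX3, nor for the NF-kB and endothelial lists. Without _x_at and _s_at probe sets, none could be had for AEN, BMP4, CALB2, EGR1, ERN2, FADS2, GUSBP11, ICAM1, IL17RB, MT1E, MVD, MYC, NUP42, PLAUR, SLC3A2, SMYD3, SOX9, SPN and SRF. Other probe sets gave none for the Wnt, estrogen-repressed, interferon, kinase inhibitor, endothelial, NF-kB and Notch lists. The probe-to-probe error stayed within 1.5 times at both other limits.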

Other observations

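The tests of single probe set noise and of CCNA1 against the other cell cycle genes were chosen only after the results were seen, and DDX50 was added to its group after its values were seen. The genes in the rest of this paragraph were also chosen after their values were seen. Both subunits of soluble guanylate cyclase, the receptor for nitric oxide, were higher in K102Q, with log2 differences of 1.32 for GUCY1A1 and 1.57 for GUCY1B1. PTGER4, a receptor for prostaglandin E2, was 2.85-fold higher. SLC7A5, the transport partner of SLC3A2 in amino acid uptake, was 1.74-fold lower (14051.5 against 8068.6), and SLC3A2 was 2.00-fold lower. TMEM64, a membrane protein gene, was 2.49-fold lower, with a median of -1.31 log2 on its 2 other probe sets.

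The lower signal of cell cycle genes in K102Q was weighed against noise, bias and copy number. Their 66 other probe sets, from 48 genes, had a median of -0.20 (-0.31 to -0.13), and 48 of these probe sets were below 0. The median was 0.02 for the other probe sets of all genes, which argues against noise of the chosen probe sets. The interval treats probe sets as independent, although several can target 1 gene, so it may be too narrow. The highest percentile of the 3 lists was 0.07 after lowess correction. The random lists were already matched on mean expression, so this percentile could hardly change and decides nothing about intensity-dependent bias. The list medians do not depend on that matching. After lowess they were -0.22 (cyclins), -0.22 (G1/S) and -0.29 (G2/M), against -0.23, -0.24 and -0.30 before. These medians argue against intensity-dependent bias as the whole cause. Only 1 of 19 cyclin, 5 of 36 G1/S and 7 of 38 G2/M genes lie on the chromosomes that hold runs of neighbouring genes. Most members lie elsewhere, which argues against those runs as the whole cause. Without those chromosomes the highest percentile was 0.13, but leaving out so few genes could change it little. Only windows of neighbouring genes with a median more than 0.39 from that of all genes counted as runs. Smaller copy number differences on other chromosomes were therefore not tested. CCNA1 minus CLSPN, the next lowest member, was -0.48 log2, within the 0.56 SD of a difference between dim genes, so an effect of its own and a part in the group shift cannot be told apart. With 1 array per group, an effect of the mutation cannot be told apart from culture state or line history.

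The 5 genes at least 8-fold higher in K102Q were LGALS4, ERCC1, AGO3, EPB41L4A and DDX50. Their 10 nearest measured neighbours had median log2 differences of 0.071, 0.10, -0.016, -0.16 and -0.086 in that order, which argues against copy number gain of the regions. The lowest other probe set above the limit on both arrays read 3.66 for ERCC1, 1.89 for AGO3 and 3.27 for EPB41L4A, which argues against noise of a single probe set. For the 2-fold genes, the highest simulated count of 56 against 142 argues against such noise as the whole cause of the count. It does not clear single genes, since the simulated median was 42. Simulated genes that fell under the limit were not counted, so noise among dim genes may be understated. LGALS4 had 0 other probe sets above the limit, so noise of a single probe set cannot be told apart from a true difference, and the other probe set of DDX50 read -0.0061, so noise may account for its value, although a difference in part of the transcript stays open. Lentiviral insertion, clonal origin of the lines and an effect of the mutation were not tested.

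Runs of neighbouring genes differed together: over 12176 windows of 20 neighbouring measured genes, the largest median, as a distance from that of all genes, was 0.56, against at most 0.51 in 200 shuffled gene orders. The 2 most pronounced windows were FAM98B to KNL1 (-0.57) and DNASE1L1 to VAMP7 (0.55). The 166 genes from MTMR10 to TLN2 had a median of -0.37, with 137 lower, and the other 248 genes of that chromosome were also lower (-0.22), whereas the 56 genes from FMR1 to VAMP7 had a median of 0.48, with 51 higher, and the rest of theirs 0.02. The ends of these 2 runs were set by the outermost pronounced windows in the same gene values. Their medians and counts are therefore partly fixed by that choice. The other probe sets of the 2 runs, not used to set the ends, had medians of -0.30 and 0.45. They read the same genes on the same arrays, so they check probe set noise only, not the choice of ends by gene level. A copy number difference between the 2 lines is a candidate explanation, and regional effects of the mutation were not tested.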
